A study of Homo sapiens with 12 samples.

How the data were processed

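Gene expression was measured on 12 Agilent whole-genome arrays, each with RNA from a human small cell lung cancer line, labelled with Cy3. Per the labels, the lines grew in RPMI with 10% serum and 1% antibiotic, RNA was extracted with Trizol, and 100 ng was labelled with version 6.6 of the maker's single-colour kit. The authors scanned the arrays with Agilent Feature Extraction 10.7, which the file headers give as 10.7.3.1. Per the file headers, the processed signal is a linear fluorescence intensity, background subtracted and detrended, in which values near the background were replaced by a surrogate. The deposited table of 1 value per probe and array holds log2 values whose medians lay between 6.63 and 6.70, so it had been brought to a common scale between arrays by a step that the labels do not state. Each of its columns followed its own array best (r of 0.985 to 0.991, against 0.968 to 0.985 for the closest other array). It served only as an alternative.

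The 12 arrays fall into 4 groups: mock, MAX and shBRG1, each in H1417, LU134 and LU165, and MAX-shBRG1 with 3 arrays. The series text calls these 3 arrays replicates of the same sample, of LU134. They were averaged and counted as 1 biological sample, assumed to vary like the other groups, so that 10 samples entered the fit. Replicates 1, 2 and 3 of a group are H1417, LU134 and LU165 in that order, and the cell line gives the pairing. A check of the pairing correlated the deviations of arrays from their group means, over all tested genes. It gave r between 0.797 and 0.922 for 9 pairs of arrays of the same line and between -0.523 and -0.331 for 18 pairs of different lines. Subtracting a mean over 3 lines by itself pushes r between different lines below 0, so only the same-line values bear on the pairing. Arrays lay on 2 slides. Both arrays of a pair shared a slide for MAX and mock of LU134 and of LU165, and for shBRG1 and mock of H1417 and of LU134.

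From the processed signal, each array was put on the log2 scale and its 75th percentile subtracted. That percentile lay between 703 and 1425 units of intensity over the arrays, 62.8% to 68.2% of spots were well above background, 194 to 476 spots per array were outliers and left out, and 0 spots were saturated. The slope of the spike-in controls lay between 0.998 and 1.02. The number of arrays limits the precision of every value. Of 50599 probes on 58717 spots, 103 had no usable spot on some array. A probe was tested if well above background on at least 3 of the 12 arrays, which 35531 were, and the probe with the highest mean signal stood for its gene, which left 25970 genes. Probes were named by transcript accession in the current gene table (28174), by symbol (2618) or by synonym (620), 17273 kept the name in the files and 1914 had none. That table, of assembly GRCh38.p14, gave names only, and coordinates are those of the files, on build hg19.

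Differences were tested with limma 3.58.1 in R 4.3.3 (data.table of version 1.17.8), 2-sided, with group and cell line (the replicate block) as terms, 4 residual degrees of freedom and 2.62 prior degrees of freedom. Genes with a Benjamini-Hochberg adjusted p under 0.05 over the 25970 genes were called. Tools for counts do not apply to these intensities. A p-value here measures only the spread between these samples, 1 culture of each kind. The 23 gene lists, with 586 genes of which 550 were measured, were tested with camera at a preset inter-gene correlation of 0.01, with p adjusted over the lists. Camera with an estimated correlation and fry were run beside it. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Where a gene was not well above background on any array of a group, the fold was computed against the lowest signal that was called well above background there, and is given as "at least"; for the sample labelled MAX-shBRG1 this was done within LU134.

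The tests, the lists and the rule for naming genes were fixed before the data were examined. Named were MAX and SMARCA4; for MAX against mock, shBRG1 against mock and MAX-shBRG1 against MAX, the genes with the largest changes among those called, or in a direction with fewer than 5 such genes the 5 with the smallest p and the same sign in all lines, given as not passing; up to 4 genes with the smallest p from each list; and for the other comparisons the genes with the largest changes among those called, or the 3 with the smallest p. Genes had to have a symbol and could not be Y-linked. Results for some genes are not reported here because they are withheld. A list of 41 keratinocyte genes was written after the called genes were seen and before its own values were.

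The fit was tested on simulated data with the spread of these samples. With MAX against mock it called 22% of genes changed 2-fold, 66% of those changed 4-fold and 100% of those changed 16-fold, and 9 of 25770 unchanged genes. For the lone sample labelled MAX-shBRG1 against MAX it called 2% at 2-fold, 40% at 4-fold and 80% at 16-fold, and 3 unchanged genes. Camera called the 1 list shifted by 0.50 (log2) and 0 others, but the simulated genes varied independently of each other. This check therefore does not show how often camera calls unchanged lists whose genes vary together. Alternatives covered the scaling between arrays (normexp with quantile scaling at an offset of 50, quantile scaling alone, centring on the median, the deposited table), the filter on dim probes, probes tested singly, the block terms, the groups in the fit, the variance model, a 2-fold threshold and the leaving out of each array and each line. A fit without the sample labelled MAX-shBRG1 was added after seeing the data.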

Results

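Gene expression was compared in 3 small cell lung cancer lines, H1417, LU134 and LU165, under 4 conditions. Small cell lung cancer is a neuroendocrine tumour, and the series describes its lines as deficient in MAX, the protein that MYC and its relatives need as a partner to bind DNA. Mock cells, cells given MAX and cells given shBRG1, a short hairpin against SMARCA4 (BRG1), the motor subunit of the SWI/SNF chromatin remodelling complex, were each represented by 1 array per line. The label MAX-shBRG1 stands for 3 arrays of a single sample of LU134. On every array 62.8% to 68.2% of spots were well above background. Signals are given as log2 relative to the array's 75th percentile, and changes as log2 differences with the standard error of the fit (SE). Arrays of the same line resembled each other (r of 0.966 to 0.991 across genes) more than arrays of different lines did (0.861 to 0.888), and the 3 MAX-shBRG1 arrays were nearly alike (0.992 to 0.994).

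The targeted genes were examined first. SMARCA4, measured by probe A_23_P39034 (chromosome 19, 11172673 to 11172732), was lower with shBRG1 in all 3 lines, by -2.82 in H1417, -2.99 in LU134 and -1.20 in LU165, a mean of -2.34 ± 0.99 (SD, n = 3) or 5.06-fold. Over all genes tested this gave an adjusted p = 0.212 in limma (range over the alternatives 0.0788 to 1.00), so SMARCA4 did not pass the threshold. With slide as a block the difference was -2.56, and in H1417 and LU134 both arrays lay on 1 slide. In the sample labelled MAX-shBRG1, SMARCA4 was not lowered: it differed by -0.11 from MAX of LU134 (arrays between -0.23 and -0.03) and by -0.28 from mock. The difference from MAX was -0.21 with normexp and quantile scaling, -0.19 with quantile scaling, -0.07 with centring on the median and -0.23 with the deposited table. For MAX, probe A_23_P151662 (chromosome 14, 65560459 to 65560518) was at least 78.8-fold brighter with MAX in H1417 and at least 18.4-fold in LU165. In LU134 it was bright in mock already, at 1.46, and differed by 0.15 with MAX. Probe A_23_P436138 (65550834 to 65550893) was above background only in LU134, and A_23_P205549 (65542003 to 65542062) differed by 0.26, -0.29 and -0.67 in the 3 lines. The fitted change of the MAX gene, 4.19 (SE 1.41), did not pass the threshold (adjusted p = 0.980). The other 2 probes had small fitted changes below 0, -0.23 (SE 0.22) for A_23_P205549 and -0.20 (SE 0.25) for A_23_P436138. In H1417 both were higher with MAX, by 0.26 and 0.42, the latter not well above background there.

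**Figure D1:**
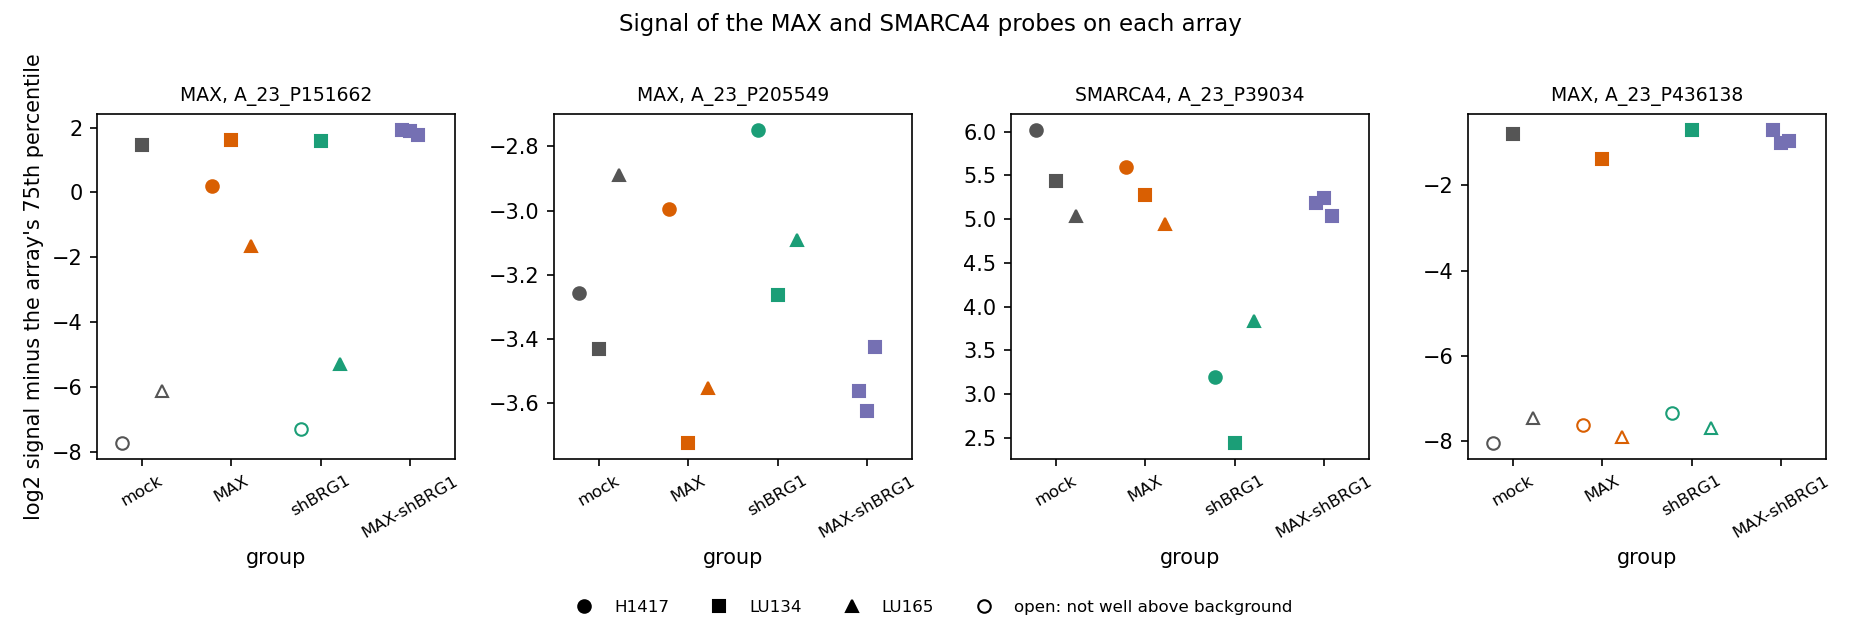
Signal of the 3 MAX probes and the SMARCA4 probe on each of the 12 arrays, by group (log2 relative to the array's 75th percentile, each panel on its own scale). Points are single arrays, shapes mark the cell line and open points were not well above background. SMARCA4 was low in the shBRG1 arrays and not in the arrays labelled MAX-shBRG1.

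MAX against mock asked which genes respond when MAX is supplied, although in LU134 a MAX probe was bright in mock already and differed by 0.15. Genes of the response to low oxygen rose as a group: 16 of the 20 measured hypoxia genes were higher, with a median change of 0.51 (1.42-fold). P4HA1 and P4HA2, which hydroxylate prolines of collagen, differed by 1.26 (SE 0.27) and 0.91 (SE 0.17), BNIP3, a mitophagy receptor, by 0.94 (SE 0.21), and ANGPTL4, a secreted inhibitor of lipoprotein lipase, by 1.66 (SE 0.47). Glycolysis genes rose too, 20 of 23 being higher with a median of 0.36. Among them were PFKFB3 at 1.51 (SE 0.34) and PFKFB4 at 1.11 (SE 0.27), which make the activator of phosphofructokinase, the lactate exporter SLC16A3 at 1.75 (SE 0.40) and lactate dehydrogenase LDHA at 0.76 (SE 0.24). HK2, the hexokinase that traps glucose in the cell and a member of the MYC target list, differed by 3.11 (SE 0.64), with 3.66 in H1417, 4.49 in LU134 and 1.19 in LU165. Camera called both lists (adjusted p = 1.38e-08 for each), with adjusted p = 0.112 for hypoxia and 0.318 for glycolysis with an estimated correlation. Adjusted over the list alone, 8 hypoxia and 3 glycolysis genes passed, and 0 did over all genes. The hypoxia medians were 0.36 in H1417, 0.73 in LU134 and 0.52 in LU165, and those of glycolysis 0.45, 0.28 and 0.34, of which the values in LU134 and LU165 were within a slide. With slide as a block the medians were 0.67 and 0.34.

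Interferon response genes rose most in LU134. Of 25 measured, 24 were higher, and the median of 0.86 (1.81-fold) was made up of 0.26 in H1417, 2.07 in LU134 and 0.26 in LU165. In LU134 the list also lay above mock with shBRG1 (median 0.54, 22 of 25 higher) and in the sample labelled MAX-shBRG1 (1.12). These values and that of MAX rest on the same mock array, and MAX minus shBRG1 of LU134 gave 1.66. With shBRG1 the medians were -0.11 in H1417 and -0.02 in LU165. OAS1, a sensor of double-stranded RNA, differed by 1.39 (SE 0.55), and by 2.97 in LU134, the RNA sensor IFIH1 by 1.37 (SE 0.34) and IFIT2 by 0.86 (SE 0.27). The ATF4 and unfolded protein response list also rose (21 of 22 higher, median 0.29, and 0.24, 0.47 and 0.22 in the 3 lines), with TRIB3, a pseudokinase induced by ATF4, at 1.38 (SE 0.36), ATF3 at 0.74, DDIT3 (CHOP) at 0.66 and SESN2 at 0.57. Camera gave adjusted p = 9.84e-09 for interferon and 1.42e-06 for ATF4, and adjusted p = 0.428 and 0.318 with an estimated correlation. The interferon median was 0.55 with normexp and quantile scaling and 0.56 with only probes above background on all arrays, and the ATF4 median 0.19 with arrays centred on their median, all still called. Centring moved the median of all genes in MAX against mock from 0.01 to -0.08, and the list medians with it. Without LU134 the interferon median was 0.21, without mock of LU134 0.36 and without MAX of LU134 0.30, each still called. It was 0.94 with slide as a block, and the ATF4 median 0.26. No gene (0) of either list passed adjusted over the list alone.

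Smaller rises were called for 3 more lists. Immediate early genes, the first to be transcribed after a stimulus, had a median of 0.15 with 13 of 16 higher, IER3 at 0.87 (SE 0.22) and EGR2 at 1.28 (SE 0.59) among them. The list of p53 targets and cell cycle inhibitors had a median of 0.10 with 21 of 28 higher, including the stress gene GADD45B at 0.71 (0.40 to 0.99 over the alternatives) and the BH3-only gene BBC3 at 0.79 (0.35 to 1.10). Neuroendocrine genes had a median of 0.17 with 27 of 38 higher, including the neuropeptide gene GRP at 1.10 (SE 0.47) and ENO2, neuronal enolase, at 0.36. Camera gave adjusted p = 0.0135, 0.0343 and 0.0441 for the 3 lists, and adjusted p = 0.560, 0.560 and 0.428 with an estimated correlation. The medians with slide as a block were 0.30, 0.07 and 0.12. Without the replicate block all 3 calls ended. Centring arrays on their median gave 0.06, 0.00 and 0.07, the last no longer called (adjusted p = 0.0543), testing probes singly ended the p53 call (0.09), and only probes above background on all arrays gave 0.08 for immediate early genes. As centring moved the median of all genes from 0.01 to -0.08, medians of this size depend on the scaling chosen. The immediate early call ended without LU165 (median 0.01), its MAX array (-0.06), its mock array (0.21) or mock of H1417 (0.13), and the median was 0.24 without H1417, 0.30 without its MAX array, 0.25 without LU134 and 0.26 without its mock array. The p53 call ended without LU134 (0.12), LU165 (0.09), mock of LU134 (0.07), mock of LU165 (0.12), MAX of H1417 (0.02) or MAX of LU165 (0.12), and the median was 0.16 without mock of H1417 or MAX of LU134. For neuroendocrine genes the call ended without H1417 (0.11), LU134 (0.12) or LU165 (0.20), without mock of H1417 (0.15) or LU134 (0.11), without MAX of H1417 (0.10) or LU165 (0.16) and without shBRG1 of LU165 (0.17).

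Genes of growth and division fell as groups by small amounts. Ribosome biogenesis genes were lower in 37 of 39 cases, with a median of -0.19, and -0.30, -0.26 and 0.00 in H1417, LU134 and LU165. RRP1B, a nucleolar protein, and POLR1A, the large subunit of RNA polymerase I, both differed by -0.34 (SE 0.15 and 0.16). MYC targets were lower in 45 of 57 cases (median -0.11), with the replication helicase subunit MCM4 at -0.55 (SE 0.17) and UTP20, a factor of small subunit assembly, at -0.38. The G2/M list was lower in 26 of 28 cases (median -0.11, and 0.07, -0.33 and -0.09 in the lines), with the proliferation marker MKI67 at -0.29 and cyclin A2 (CCNA2) at -0.31. Camera gave adjusted p = 1.38e-08, 0.00184 and 0.00327 for the 3 lists, and adjusted p = 0.428, 0.560 and 0.577 with an estimated correlation. Adjusted over the list alone, 0 genes of any of them passed, and the medians with slide as a block were -0.20, -0.12 and -0.13. Ribosome biogenesis stayed called in all 12 fits that leave out an array or a line, at -0.12 without H1417, -0.13 without its mock array, -0.29 without LU165 and -0.32 without its mock array. The call of MYC targets ended without H1417 (-0.10), without its mock array (-0.07) and without LU134 (-0.08). For G2/M the call ended without LU134 (-0.02), without its MAX array (0.02) and without mock of LU165 (-0.07), and the median was -0.20 without H1417 and -0.19 without its MAX array. Centring arrays on their median gave -0.21 for MYC targets and for G2/M, whose call ended with quantile scaling (-0.09) and with the deposited table (-0.10). These lower values reflect a shift of all genes, whose median moved from 0.01 to -0.08 with centring.

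Among chromatin genes, SWI/SNF subunits fell (21 of 29 lower, median -0.11), with PBRM1, of the PBAF form of the complex, at -0.34 and DPF3 at -0.62. DPF3 stood at -0.40 with normexp and quantile scaling and at -0.23 by another probe, the one above background on all arrays. Histone genes (7 of 11 lower, median -0.12) fell, with H3C4 at -0.44, as did the G1/S list (24 of 30 lower, median -0.07), with UHRF1, a reader of hemimethylated DNA, at -0.25. Camera gave adjusted p = 0.0343, 0.0444 and 0.0410 for SWI/SNF, histones and G1/S, and adjusted p = 0.560, 0.577 and 0.577 with an estimated correlation. No gene (0) passed adjusted over the list alone, and with slide as a block the medians were -0.08, -0.24 and -0.11. The SWI/SNF call ended without LU134 (-0.03), LU165 (-0.03), mock of LU134 (-0.06) or LU165 (-0.04) and MAX of LU134 (-0.05) or LU165 (-0.05), and the median was -0.17 without H1417 and -0.18 without its MAX array. For histones the call ended without LU134 (-0.13), LU165 (-0.07), mock of H1417 (-0.11), LU134 (-0.16) or LU165 (-0.15), MAX of LU134 (-0.06) or LU165 (-0.04) and shBRG1 of LU134 or LU165 (-0.12 each), and the median was -0.24 without H1417 and -0.28 without its MAX array. For G1/S it ended without H1417 (-0.08), LU134 (-0.08), LU165 (-0.07), mock of H1417 (-0.03) or LU165 (-0.09) and MAX of LU134 (-0.04) or LU165 (-0.04), and the median was -0.13 without MAX of H1417. All 3 calls ended without the replicate block, with quantile scaling (-0.12, -0.11 and -0.05) and with the deposited table (-0.10, -0.10 and -0.08), and centring arrays on their median gave -0.20, -0.21 and -0.17, still called. They also ended with only probes above background on all arrays (-0.12, -0.12 and -0.07), for histones (-0.12) and G1/S (-0.07) without a filter on dim probes, for G1/S with normexp and quantile scaling (-0.08), and for histones with probes tested singly or only the 2 groups compared (-0.12 each). Probes tested singly gave -0.06 for SWI/SNF. The lower medians with centring reflect a shift of all genes, whose median moved from 0.01 to -0.08.

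**Figure D2:**
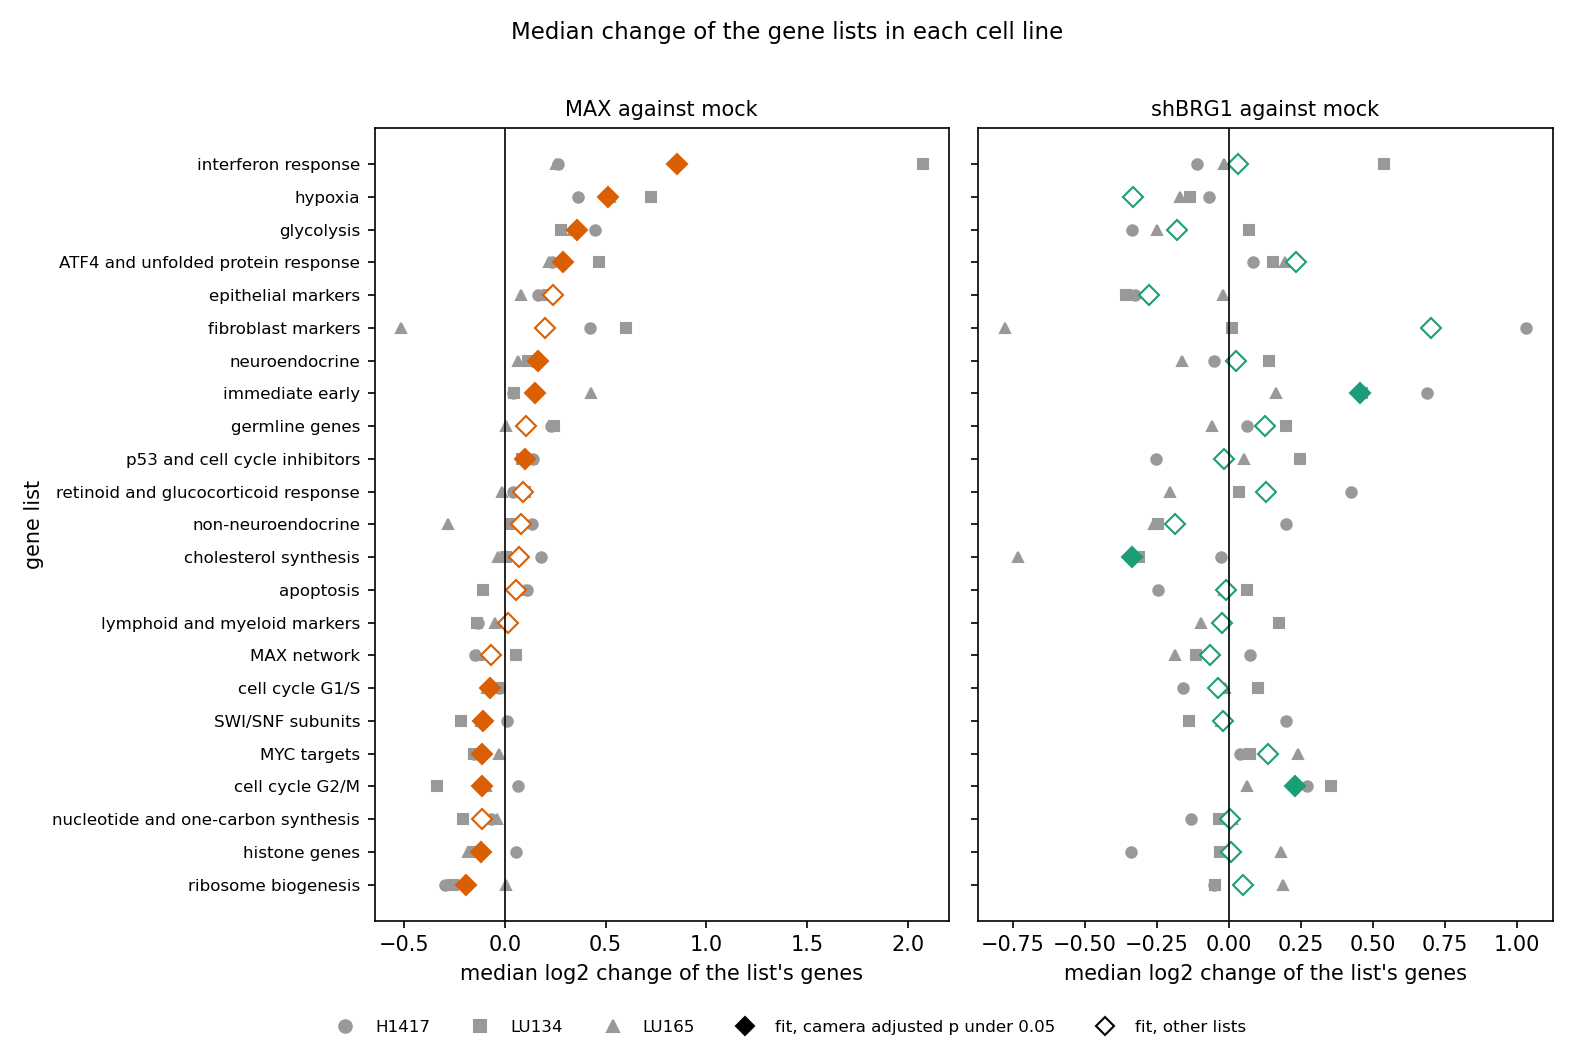
Median log2 change of the genes of each of the 23 lists for MAX against mock (left) and shBRG1 against mock (right). Diamonds give the fit over the 3 lines, filled where camera called the list, and grey shapes the median in each line. The interferon list in LU134 lay at 2.07, and the hypoxia and glycolysis lists lay above 0 in every line with MAX.

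Members of the MAX network differed in both directions with MAX: MYC by -0.63 (SE 0.26), MYCN by -0.80 (SE 0.38) and MYCL by 1.37 (SE 0.66), the last with 3.49 in LU134 and -0.21 in LU165. That list was not called (adjusted p = 0.494), and its median of -0.07 and its mean of 0.33 differed in sign. Germline genes (median 0.11), nucleotide synthesis (-0.11), cholesterol synthesis (0.07), the retinoid and glucocorticoid response (0.09), apoptosis (0.06), the non-neuroendocrine list (0.08) and the markers of lymphoid and myeloid cells (0.01, with a mean of -0.03), fibroblasts (0.20) and epithelia (0.24) were not called either. No single gene passed: limma called 0 of 25970, with a smallest adjusted p of 0.480, while 1255 had an unadjusted p under 0.05 against 1298.5 that chance alone gives. The genes with the smallest p included SOX3, a transcription factor of neural progenitors, at 1.56 (SE 0.18), the growth factor gene PDGFB at 1.63 (SE 0.26), the chemokine receptor gene ACKR3 at 1.92 (at least 1.16-fold), CATSPER1 at 1.27 and CFAP96 at 1.13. On the lower side stood SPATA31E1 at -2.04 (SE 0.19), HAUS3, of the spindle's augmin complex, at -1.69, the potassium channel gene KCNJ5 at -1.16, LSP1 at -1.09, for which 1 further probe went the opposite way, and SNORA69, a small nucleolar RNA, at -1.06. Normexp with quantile scaling made 16 of the 46 genes named for MAX against mock smaller by over 1.5 times, among them SOX3 (0.36), PDGFB (0.46), ACKR3 (0.34), CATSPER1 (0.30), SPATA31E1 (-0.48), KCNJ5 (-0.30), SNORA69 (-0.37), MYCL (0.31), ANGPTL4 (0.64), OAS1 (0.58), IFIH1 (0.79), IFIT2 (0.39) and EGR2 (0.38). The deposited table did so for 11, with SOX3 at 0.75 and SPATA31E1 at -0.89. Leaving out LU134 or its mock array did so for 9 each, and leaving out its MAX array for 6. Camera called 13 lists (7 higher, 6 lower), against 0 with an estimated correlation (3 at an unadjusted p under 0.05), 0 by fry and 1 by its test in either direction. The split moved with the scaling, to 7 higher and 2 lower with quantile scaling and with the deposited table, and the number fell by leaving out LU134 (6), LU165 (7), MAX of LU165 (7) or mock of H1417 (8). Without the replicate block 7 lists were called, and with slide as a block 0 genes and 14 lists.

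For shBRG1 against mock the question was which genes respond to the hairpin against SMARCA4. As no group carried a control hairpin, a response to the vector or to selection could not be told apart from one to lower SMARCA4. HBB, the beta chain of adult haemoglobin (chromosome 11, 5246718 to 5246777), rose by 4.53 (SE 0.29), at least 8.43-fold in the processed signal, with 5.04 in H1417, 3.76 in LU134 and 4.78 in LU165. It was well above background on all 3 shBRG1 arrays and on no other array. RNU6ATAC, the U6-like small nuclear RNA of the minor spliceosome (chromosome 9, 137029562 to 137029621), rose by 2.38 (SE 0.16, 5.22-fold), with 2.73, 2.12 and 2.30. These were the 2 genes that limma called (adjusted p = 0.0342 for each), while 0 fell and 3399 of 25970 had an unadjusted p under 0.05. Next by p, and not passing (adjusted p = 0.212), were the aldo-keto reductase gene AKR1B10 at 2.26 (at least 1.31-fold), SCARNA9, a guide RNA of Cajal bodies, at 2.69, and SOX3 at 1.23. On the lower side these were the sterol transporter gene ABCG1 at -1.53 (SE 0.17), the adaptor gene CRK at -1.22, SH3GL1 at -1.88, ASAP3 at -1.32 and NHSL3 at -1.35. Over the alternatives the adjusted p of HBB ranged from 0.00272 to 0.631 and that of RNU6ATAC from 0.00272 to 0.743. HBB stood at 1.65 with normexp and quantile scaling and at 2.78 with the deposited table, no longer called in either (adjusted p = 0.0826 and 0.0931), and both calls ended without a filter on dim probes, without the replicate block and with only the 2 groups compared. Normexp with quantile scaling also gave AKR1B10 at 0.42 and SOX3 at 0.24. With slide as a block the changes of HBB and RNU6ATAC were 4.58 and 2.39 and neither passed (adjusted p = 0.158), and the within-slide values are those of H1417 and LU134. With 1 array or line left out 0 genes passed in 11 of 12 fits, and 1, HBB, did without shBRG1 of LU134.

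**Figure D3:**
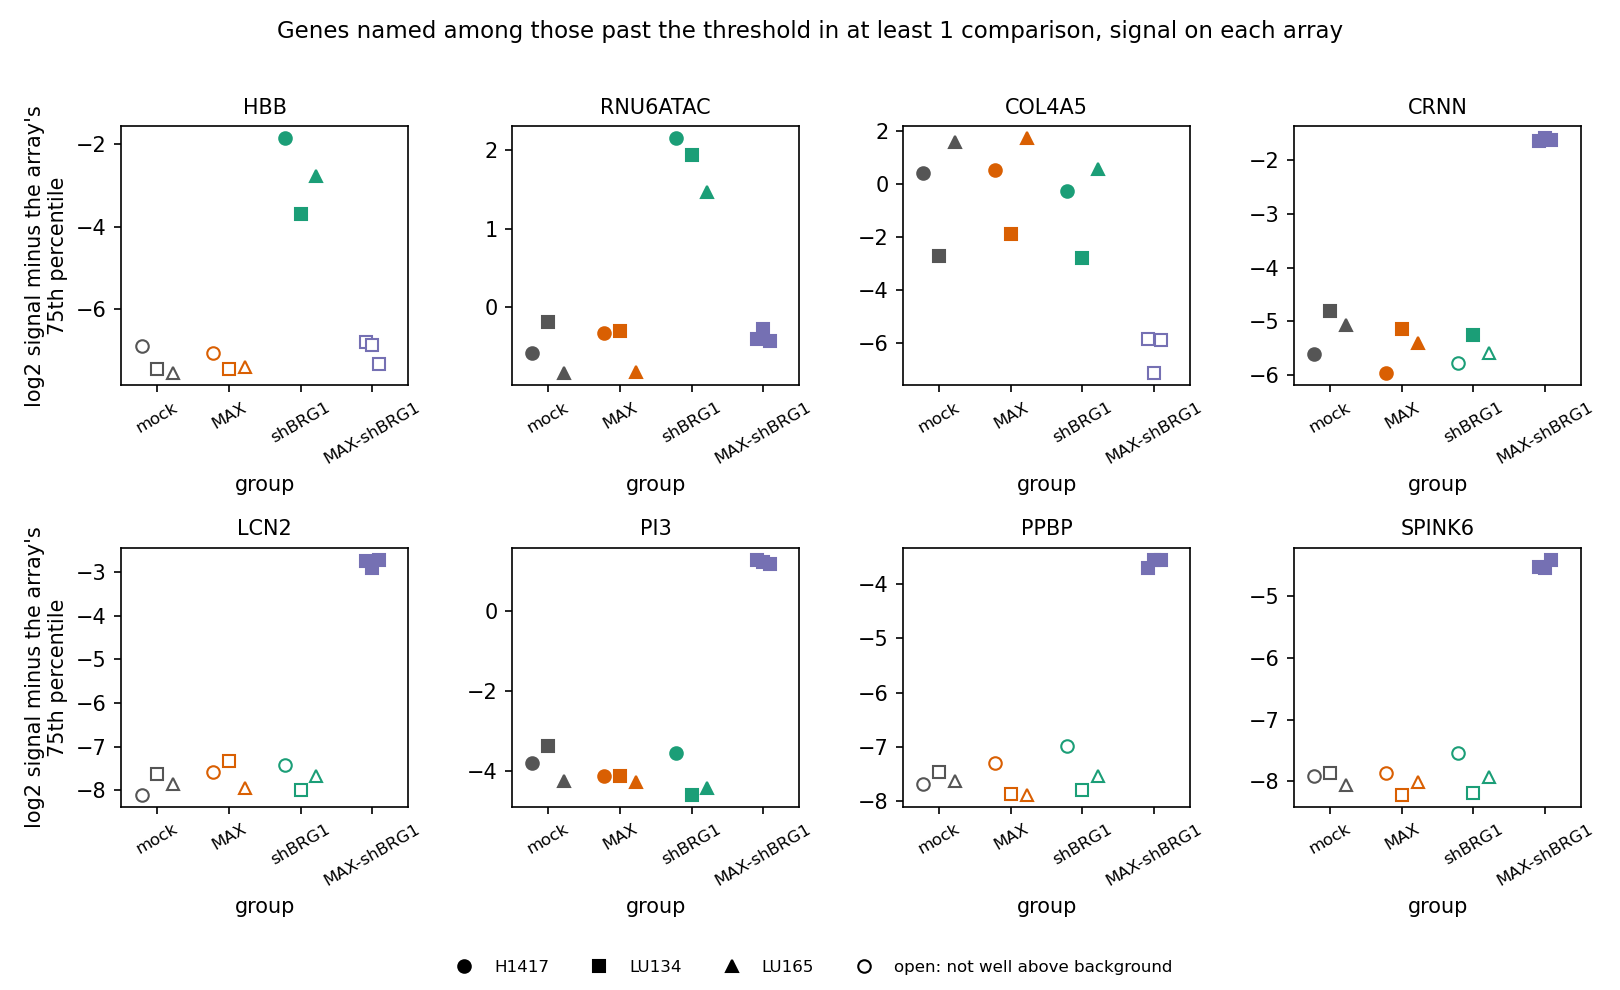
Signal of 8 of the 9 genes that passed the threshold in at least 1 comparison, on each of the 12 arrays by group (log2 relative to the array's 75th percentile, each panel on its own scale). Points are single arrays, shapes mark the cell line and open points were not well above background. HBB and RNU6ATAC stood out in the shBRG1 arrays, and 5 other genes in the arrays labelled MAX-shBRG1, where COL4A5 was dim.

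Cholesterol synthesis genes fell as a group with shBRG1: 20 of 22 were lower, with a median of -0.34, and -0.03, -0.31 and -0.73 in H1417, LU134 and LU165. DHCR7, which makes cholesterol in the last step of its synthesis, differed by -0.84 (SE 0.15), SC5D by -0.75 (SE 0.17) and HSD17B7 by -0.75. G2/M genes rose, 23 of 28 being higher with a median of 0.23 (0.27, 0.35 and 0.06 in the lines), such as CDC20, the activator of the anaphase-promoting complex, at 0.61 (SE 0.14) and UBE2C at 0.55, while FOXM1, their transcription factor, stood at -0.43. Immediate early genes rose, 12 of 16 being higher with a median of 0.46 (0.69, 0.46 and 0.16), such as FOSB at 1.07 (SE 0.22), MYADM at 1.27 (SE 0.31), EGR2 at 1.86 and KLF2 at 0.68. With normexp and quantile scaling these 4 stood at 0.58, 0.45, 0.63 and 0.42, and another probe of MYADM, the one above background on all arrays, at 0.05. Camera gave adjusted p = 7.53e-05, 0.00365 and 0.00517 for the 3 lists, all with adjusted p = 0.879 with an estimated correlation. Adjusted over the list alone, 2 cholesterol genes, 0 G2/M genes and 2 immediate early genes passed. Slide as a block gave medians of -0.27, 0.24 and 0.58. The cholesterol call ended without LU165 (-0.18) and without its shBRG1 array (-0.23), the G2/M call without LU134 (0.17) and without its shBRG1 array (0.11), and the immediate early call without H1417 (0.35), without its shBRG1 array (0.29) and without shBRG1 of LU134 (0.50). The cholesterol median was -0.57 without H1417, -0.50 without its mock array and -0.21 without mock of LU165, and that of G2/M 0.35 without LU165 and 0.36 without its shBRG1 array. The G2/M and immediate early calls ended without the replicate block, and the immediate early call with only probes above background on all arrays (0.40).

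Single members of lists that camera did not call passed with shBRG1 adjusted over the list alone. Among neuroendocrine genes these were PCSK1 and CPE, enzymes that process peptide hormones, at -2.16 (SE 0.27) and -0.79 (SE 0.16), while GRP stood at -1.78 (-2.23 to -1.18 over the alternatives) and the neurogenic factor NEUROD1 at 1.28 (0.60 to 1.63). In the p53 list they were the cell cycle inhibitor CDKN1A at 0.91 (SE 0.17) and the ribonucleotide reductase subunit RRM2B at -0.86 (SE 0.17). In the ATF4 and unfolded protein response list PPP1R15A stood at 0.82, and the chaperone gene HSPA5 at -0.91, the cystine transporter SLC7A11 at -0.97 and the glutathione-degrading enzyme CHAC1 at -1.38. SMARCA4 was the member that passed among SWI/SNF subunits, where its paralogue SMARCA2 stood at 0.67 (SE 0.20) and SS18 at -0.63 without passing. HBB, which had passed over all genes, passed among the blood markers, and 1 gene did among the fibroblast markers. In the MAX network, MXD4 and MLXIP stood at -0.54 and -0.55, and among glycolysis and hypoxia genes the glucose transporter SLC2A1 at -1.24, with 1 further probe opposite, STC2 at -1.28 and DDIT4 at -0.84, none of them passing. Over all genes the adjusted p of the genes named here and not called lay between 0.212 and 0.362. Fry called 1 list, the blood markers that hold HBB (adjusted p = 0.0491), and its test in either direction called 15. Camera called 7 lists without mock of H1417 and 5 without H1417, 5 with normexp and quantile scaling, and 1 without the replicate block.

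Compared directly, MAX and shBRG1 differed in the same genes: HBB was lower with MAX than with shBRG1 by -4.53 (SE 0.29, at least 8.77-fold) and RNU6ATAC by -2.33 (SE 0.16), both with adjusted p = 0.0394. The next by p, NHSL3, was higher by 1.49 (SE 0.16, adjusted p = 0.123). Camera called 7 lists: glycolysis (median 0.59), hypoxia (0.63), cholesterol synthesis (0.47) and interferon (0.65) were higher with MAX, and MYC targets (-0.23), ribosome biogenesis (-0.26) and G2/M (-0.32) higher with shBRG1. These had adjusted p between 0.185 and 0.578 with an estimated correlation, and fry called 3 lists. Adjusted over the list alone, 13 glycolysis genes, 8 hypoxia genes and 3 cholesterol genes passed as higher with MAX. The glycolysis list was also lower with shBRG1 than in mock in H1417 (-0.34) and LU165 (-0.25), with 0.07 in LU134. Limma called 0 genes higher and 2 lower, with 4264 at an unadjusted p under 0.05. The count was 88 with normexp and quantile scaling, 79 with only probes above background on all arrays, and 0 with slide as a block (adjusted p = 0.0995), where HBB stood at -4.53. HBB was at -1.64 with normexp and quantile scaling, still called, and at -2.75 with the deposited table, not called (adjusted p = 0.0526), and testing probes singly ended both calls (0.0537). The count was 0 in 11 of the 12 fits that leave out an array or a line and 1 without shBRG1 of LU134. Centring arrays on their median moved the median of all genes to -0.12 in this comparison.

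The sample labelled MAX-shBRG1 against MAX asked what the hairpin adds in cells given MAX, but SMARCA4 was not lowered in it, so directions are those of the sample as labelled. Among the genes that rose were PI3 (elafin, a protease inhibitor of skin) by 5.38 (SE 0.44), the iron-trapping protein LCN2 by 4.75 (SE 0.37, at least 9.15-fold in LU134), the platelet chemokine PPBP by 4.23 (SE 0.33, at least 5.23-fold in LU134), the epidermal inhibitor SPINK6 by 3.67 (SE 0.26, at least 2.81-fold in LU134) and cornulin (CRNN) by 3.56 (SE 0.22). COL4A5, a collagen of basement membranes, fell by 4.27 (SE 0.32), at least 14.3-fold in LU134. Of the 7 genes that passed in limma these are 6 (adjusted p = 0.0356 for each), with 1006 at an unadjusted p under 0.05. LCN2, PPBP and SPINK6 were not well above background on any array outside this sample and passed the filter through its 3 arrays alone. Their SE and adjusted p therefore measure only the spread of signals near background in the other samples. On the 3 arrays of the sample the median level of 41 keratinocyte genes was -0.41, -0.39 and -0.46, against -4.04 in MAX and -2.81 in mock of LU134. Next on the lower side, and not passing, stood TMEM229B at -2.23, with 1 further probe opposite, the metalloproteinase gene MMP10 at -2.51 (at least 5.89-fold in LU134, where it differed by -2.58), MRAS at -1.58 and ROBO3 at -1.55. MMP10 was -1.25 with normexp and quantile scaling, and without the replicate block MMP10, MRAS and ROBO3 were -4.50, -2.70 and -0.17. No gene (0) passed with slide as a block (smallest adjusted p = 0.209), PI3 then standing at 5.28 and COL4A5 at -4.51, and on the arrays of LU134 that shared a slide PI3 differed by 5.35 and COL4A5 by -5.27. The count was 12 without mock of LU134 and 0 in the other 10 fits that leave out an array or a line, 18 with normexp and quantile scaling, and 0 without a filter on dim probes. Under normexp and quantile scaling the values were smaller: LCN2 1.58 and CRNN 1.96, still called, and PPBP 1.13, SPINK6 0.97 and COL4A5 -2.12, no longer called (adjusted p = 0.0865, 0.225 and 0.0934). The deposited table ended the calls of LCN2 (2.73) and SPINK6 (2.21) and gave PPBP at 2.15, the variance model with trend and robust ended those of LCN2, PPBP, SPINK6 and CRNN, and the cell line as a random effect (-4.45) and the 3 arrays with the sample as a random block (-4.27) that of COL4A5. All 6 calls ended without the replicate block.

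Among gene lists, hypoxia and glycolysis fell in the sample labelled MAX-shBRG1 against MAX, beside the difference in keratinocyte genes and with SMARCA4 not lowered. This comparison shares its MAX arrays with MAX against mock, so the fall is not independent of the rise there. In LU134 the hypoxia median was 0.73 in MAX minus mock and 0.03 in the sample minus mock, and that of glycolysis 0.28 and 0.05. Hypoxia genes were lower in 18 of 20 cases (median -0.49), with P4HA1 at -1.38, STC2 at -1.54, DDIT4 at -0.96 and BNIP3 at -0.95, and glycolysis genes in 22 of 23 (median -0.36), with PFKFB3 at -2.33, PFKFB4 at -1.57 and PDK1 at -1.90. HK2 differed by -2.71 (SE 0.98), and by -3.84 to -1.43 over the alternatives. Cholesterol genes were lower in 17 of 22 cases (median -0.29), such as FDFT1 at -0.49 and INSIG1 at -0.65. Non-neuroendocrine genes rose, 20 of 30 being higher (median 0.15, mean 0.52), among them EMP1 at 3.90 (SE 0.68), YAP1 at 1.99 and AMOTL2 at 2.92. Basal keratin genes KRT14 and KRT5, of the epithelial list that was not called (adjusted p = 0.0908), stood at 5.03 (SE 1.23) and 1.68, and KRT14 differed by 5.79 in LU134 (at least 55.5-fold). With normexp and quantile scaling KRT14 was 3.18, YAP1 1.30 and AMOTL2 1.94. Camera gave adjusted p = 1.90e-06 for hypoxia and for glycolysis and 0.0148 for the other 2 lists, and adjusted p = 0.179, 0.483, 0.739 and 0.550 with an estimated correlation. Adjusted over the list alone, EMP1 passed, as did EGR1 at 2.30 (SE 0.49) among immediate early genes, and 0 of the hypoxia, glycolysis or cholesterol genes. With slide as a block the medians were -0.75, -0.31, -0.45 and 0.34, and the non-neuroendocrine call ended (adjusted p = 0.122, range over the alternatives 0.000237 to 0.550). The cholesterol call ended without mock of H1417 (-0.26) and without MAX of LU165 (-0.29), and the non-neuroendocrine median was 0.27 without H1417 or its MAX array, 0.28 without its mock array, 0.25 without mock of LU134 and 0.35 without its MAX array. Without the replicate block, which sets LU134 against all 3 lines, the glycolysis call ended (-0.01), as did the cholesterol call (-0.16). With array 3 of the sample alone the cholesterol call ended (-0.24), and with array 2 alone the non-neuroendocrine call did (0.18). The non-neuroendocrine median was 0.37 without the block, 0.08 with normexp and quantile scaling, 0.27 without a filter on dim probes, 0.04 with only probes above background on all arrays, 0.29 with probes tested singly and 0.27 with array 1 alone, still called. Of the 4 lists 1 was higher, against 5 of 8 with normexp and quantile scaling and 4 of 8 with the deposited table, and 8 lists were called without MAX of LU134 and without shBRG1 of H1417.

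Against mock, the sample labelled MAX-shBRG1, with SMARCA4 not lowered, had 6 genes that passed, of which 5 are given here. LCN2 rose at least 6.99-fold in LU134, PPBP at least 4.0-fold and SPINK6 at least 2.14-fold, CRNN rose by 3.21, and COL4A5 fell by 3.90, at least 7.97-fold in LU134 (adjusted p = 0.0412 for each in limma, 1135 genes at an unadjusted p under 0.05). Here too LCN2, PPBP and SPINK6 passed the filter through this sample alone, so their adjusted p measures only the spread of signals near background. With normexp and quantile scaling all 5 genes were smaller, LCN2 at 1.66 and CRNN at 1.85, still called, and PPBP at 1.08, SPINK6 at 0.86 and COL4A5 at -1.87, no longer called. The deposited table ended the calls of LCN2 (3.06), PPBP (2.0), SPINK6 (1.76) and COL4A5 (-2.76), and the variance model with trend and robust those of the 4 that rose. Keratinocyte genes stood at a median of -0.41, -0.39 and -0.46 on its arrays, against -2.81 in mock of LU134. Beside them, camera called 7 lists: ATF4 (median 0.46), immediate early (0.51), interferon (0.61), epithelial markers (0.43) and non-neuroendocrine genes (0.24) were higher, and G2/M (-0.17) and cholesterol synthesis (-0.20) lower, with adjusted p between 0.447 and 0.836 with an estimated correlation. Directly in LU134, the hypoxia list had a median of 0.03 in that sample minus mock, against 0.73 in MAX minus mock. The count of genes was 0 in 10 of the 11 fits that leave out an array or a line, 1 without mock of LU134, and 0 with slide as a block. The interaction, which asks whether both changes add up, gave 0 genes in limma, with 1030 at an unadjusted p under 0.05. CRNN at 3.94 (SE 0.27, adjusted p = 0.0682), SPINK6, not well above background in the other groups, at 3.61 and PI3 at 5.76 (adjusted p = 0.135) had the smallest p. It gave 1 gene without mock of LU134, 9 with normexp and quantile scaling and 5 with quantile scaling. With normexp CRNN was 2.05, then called, and SPINK6 1.0. Camera called 5 lists there, 0 with an estimated correlation.

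The effects of MAX and of shBRG1 were correlated across genes within a line (r from 0.243 to 0.348, mean 0.309, mean Spearman rho 0.272), where both share a mock array. Unchanged groups simulated with a shared mock gave a mean r of 0.504. Sharing a mock produces such a value by itself, so the simulation shows only that the same-line r cannot be read as a shared response. Across different lines, which share no mock array, r lay between -0.0842 and 0.0627. The effects of MAX in different lines correlated at 0.0311 to 0.201 and those of shBRG1 at 0.130 to 0.201, and genes are not independent replicates. The change from MAX to the sample labelled MAX-shBRG1 correlated with shBRG1 minus mock at 0.0946 in H1417, -0.0464 in LU134, its own line, and 0.192 in LU165.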

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

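The test on keratinocyte genes and the counts of other splits were fixed before their results were seen, and the other tests in this part were chosen only after the result was seen. In the test of whether the changes of MAX and of shBRG1 add up, 5 gene lists differed between the 2 backgrounds by camera, on the sample labelled MAX-shBRG1, in which SMARCA4 was not lowered and 34 of 41 keratinocyte genes were higher than in MAX. Their median log2 differences were 0.48 for the non-neuroendocrine list, 0.50 for the epithelial markers, -0.30 for the G2/M list, -0.19 for glycolysis and -0.37 for hypoxia, with adjusted p between 0.316 and 0.875 with an estimated correlation. In MAX against mock, 4 of the called lists had a median of the opposite sign in 1 line: SWI/SNF subunits at 0.0121, G2/M at 0.0661 and histone genes at 0.0576 in H1417, and ribosome biogenesis at 0.00405 in LU165. These differences between lines were not tested.

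The sample labelled MAX-shBRG1 did not carry the marks of the shBRG1 arrays: SMARCA4 differed by -0.11 from MAX of LU134, against -2.99 for shBRG1 minus mock of that line, and neither HBB nor RNU6ATAC was raised. A knockdown that the SMARCA4 probe misses might still be present, since 318 genes that had differed at least 2-fold the same way with shBRG1 in H1417 and LU165 moved in that direction by a mean of 0.333 (log2), a ratio of 0.641 to their change with shBRG1 in LU134, and 0 of 10000 random lists reached as much. A sample with no knockdown, by a wrong label or a lost hairpin, may equally show such a change, because no group carries a control hairpin and the 318 genes may answer to the hairpin's vector or selection, although with MAX in LU134 they differed from mock by a mean of -0.0188 (5968 of 10000 random lists as high). The random lists were matched on signal only and their genes drawn singly. They do not show how often genes that vary together would shift as much in 1 sample. HBB and RNU6ATAC speak against a hairpin like that of the other arrays, and over all genes the change of this sample from MAX correlated with shBRG1 minus mock of the same line at -0.0464, while the 318 genes, read on 1 sample and 1 array, moved in the shared direction, so the explanations cannot be told apart. No biological explanation was tested.

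In the same sample PI3, LCN2, PPBP, SPINK6 and CRNN rose and COL4A5 fell. The slide is argued against, because with both arrays on slide 2 the smallest ratio to the full change was 0.975 over all 7 genes called. Added RNA of other cells would lower all genes of LU134 alike and is argued against for COL4A5, which lay -4.43 from the median of the genes above background. RNA of squamous cells is a candidate source of the genes that rose: 10 of 41 keratinocyte genes were dim in LU134, the other 31 being above background there already, and these 10 had a median change of 2.14 (SD 2.28), with 5 visible on all 3 arrays against 0.597% of 17596 dim probes. Of the 41 genes 34 were higher than in MAX, such as KRT6A (6.87) and KRT16 (5.65), and 7 were lower, down to KRT15 (-0.87) and DMKN (-1.07), and a change of the LU134 cells themselves under both treatments stays open as untested.

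The hypoxia and glycolysis lists rose with MAX. The slide is argued against as the whole cause, because within a slide the hypoxia list differed by 0.524 in LU165 and 0.73 in LU134, above all random lists of genes of like signal. Such random genes need not vary together as the genes of a list may. Mock arrays that stand apart are argued against for the hypoxia list, because its MAX minus shBRG1 gave at least 0.653 in the lines with the rise. For glycolysis MAX minus shBRG1 gave 0.90, 0.39 and 0.55 in H1417, LU134 and LU165, but these values hold changes with shBRG1 as well. The glycolysis list differed from mock with shBRG1 by -0.34, 0.07 and -0.25. The state of the cultures at harvest may be the cause, since the ATF4 and unfolded protein response list moved too, by 0.218 or more in each line. But in the sample labelled MAX-shBRG1 minus mock the ATF4 list stood at 0.48 beside a hypoxia list near 0, and there was 1 culture of each kind. In shBRG1 minus mock of H1417, LU134 and LU165 the ATF4 medians were 0.08, 0.15 and 0.19, and those of hypoxia -0.07, -0.13 and -0.17. Most of these lay inside random lists, except ATF4 in LU134, above them, and hypoxia in LU165, below them. An effect of MAX itself also stays open: the hypoxia list differed by only 0.0349 between the sample labelled MAX-shBRG1 and mock of LU134. Whether that sample holds a knockdown, or more MAX than mock, is not settled. MAX probe A_23_P151662 stood at 1.77 to 1.94 on its arrays, against 1.46 in mock. The hypoxia rise was 0.73 in LU134 and 0.36 in H1417. In LU134 that probe was bright in mock already and differed by 0.15 with MAX. It does not measure how much MAX was added there, so these values do not relate the rise to the amount of MAX. In H1417 the probe was at least 78.8-fold brighter with MAX. The state of the cultures and an effect of MAX cannot be told apart with these samples.

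The 6 samples of a comparison can be split into 3 and 3 in 10 ways, too few for a share under 0.05. For MAX against mock all 10 splits gave at least the real count of 0 genes, with 2 as the highest of the others, and 1 split, the real one, gave as many as 13 lists, with 11 as the highest other and 7 among the others of the 4 that part every pair. For shBRG1 against mock 1 split gave as many as the real 2 genes, with 0 as the highest other, and 9 splits gave as many as the real 3 lists, with 7 as the highest other. For MAX against shBRG1 1 split gave as many as the real 2 genes, with 0 as the highest other. Of lists, a count not fixed before for this comparison, the real split gave 7, with 8 as the highest other.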

How the results depend on the processing

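The fit without the sample labelled MAX-shBRG1 was chosen after seeing the data; the other alternatives were fixed before. MAX against mock gave 0 genes under all 30 alternatives, and SMARCA4 in shBRG1 against mock kept its direction (-2.91 to -2.0) and stayed above the threshold in all 29. Of 20 called lists, 441 of 548 results stayed called the same way, 106 were no longer called and 1 turned in camera's direction: G2/M in MAX against mock, 0.0180 without MAX replicate 2 (-0.205 to 0.0180 with arrays left out). The median of the immediate early list also turned there, to -0.0608 without MAX replicate 3. Of the genes named, 3077 of 3343 results kept direction and side, 246 were no longer called, 19 became called, and MAX in MAX against mock turned to -0.23 with only probes above background on all arrays, which left another probe to stand for it. Counts of called genes are given for shBRG1 against mock (2), MAX against shBRG1 (2), the sample labelled MAX-shBRG1 against MAX (7) and against mock (6), and the interaction (0). Normexp with quantile scaling gave 1, 88, 18, 12 and 9, quantile scaling 5 in the interaction, and the deposited table gave 1, 1 and 11 in the first 3. No filter on dim probes gave 0 in the first 4, and only probes above background on all arrays gave 1, 79, 1 and 1. Probes tested singly gave 0 in MAX against shBRG1 and 0 in the sample against mock. Without the replicate block the counts were 0, 0, 0 and 1. With the cell line as a random effect, which keeps a replicate block, MAX against shBRG1 gave 14, the sample against mock 11 and the interaction 7. With the slide as a block the counts were 0, 0, 0 and 0, and with only the 2 groups compared 0 and 0 in the first 2. The variance model with trend and robust gave 88, 2 and 1 for MAX against shBRG1, the sample against MAX and the sample against mock, and the 3 arrays with the sample as a random block gave 1.0e+02 (89 higher and 13 lower) in MAX against shBRG1, 11 in the sample against mock and 6 in the interaction. Array 1 of that sample alone gave 3 and array 3 alone 11 against mock, and array 2 alone 2 in the interaction. Leaving out arrays or lines gave 0 to 1, 0 to 1, 0 to 12, 0 to 1 and 0 to 1. Of the gene lists, MAX against mock (13) gave 7 without the replicate block, 0 with an estimated correlation, 0 with fry and 6 to 13 with arrays left out. In shBRG1 against mock (3) there were 5 with normexp, 1 without the block, 0 with an estimated correlation, 1 with fry and 2 to 7 with arrays left out. The sample against MAX (4) gave 8 with normexp, 8 with the deposited table, 7 with probes singly, 10 with trend and robust, 0 with an estimated correlation, 0 with fry and 3 to 8 with arrays left out. The correlation of both effects within a line moved to 0.377 without the filter. The cause of these differences was not tested. Not run were camera with random effects, the 2-fold threshold for lists, the sample's comparisons without replicate 2, and the interaction with only 2 groups. Signal over background limits genes dim in 1 group, whose folds are lower bounds.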

Other observations

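None of the values in this part was planned as a test before the data were examined. Haemoglobin genes other than HBB gave small values in shBRG1 against mock: HBA2, of the alpha chain, 0.36, HBD -0.12, HBG1, of the fetal chain, 0.18, HBM 0.06 and HBZ -0.05 (log2). ALAS2, the enzyme that starts haem synthesis in red cell precursors, gave -0.10. RNU4ATAC, the partner of RNU6ATAC in the minor spliceosome, gave -0.18, while SCARNA9, a guide RNA of Cajal bodies, gave 2.69. In the sample labelled MAX-shBRG1 against MAX, RNU6ATAC gave -0.09 and SCARNA9 0.32, and HBB, at 0.72, was not well above background on any of the 3 arrays.

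Keratinocyte genes differed most between the arrays of LU134. The median log2 signal of the 41 markers, relative to the 75th percentile, was -0.41, -0.39 and -0.46 on the 3 arrays of the sample labelled MAX-shBRG1, -2.81 in mock, -4.04 in MAX and -4.19 in shBRG1 of LU134, and between -5.46 and -4.79 in H1417 and LU165. Against mock, KRT6A differed by 4.43 in that sample, KRT16 by 3.04, KRT1 by 1.32 and KRT4 by 1.19. A further set of 45 genes, those that differed at least 2-fold the same way with MAX in H1417 and LU165, had a mean change of 0.38 (SE 0.23 over genes) in that direction in MAX minus mock of LU134, 0.38 (SE 0.16) in the sample labelled MAX-shBRG1 minus mock and 0.16 (SE 0.19) in shBRG1 minus mock. All of these share the mock array of LU134, so they are not independent. Without that array, the sample minus shBRG1 of LU134 gave 0.22 (SE 0.23).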
